A study of Arabidopsis thaliana with 3 samples.

How the data were processed

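Single-cell transcriptomes were measured in 3 wild-type libraries of Arabidopsis thaliana Col-0, the common laboratory accession. Per the labels' protocols, seedlings were grown on sucrose-free Murashige and Skoog plates under continuous light until they were 6 days old. Root tips were then digested with cell-wall-degrading enzymes, and the released protoplasts, which are cells without walls, were sorted to remove those stained by the dead-cell dye DAPI. Per the same protocols, the digestion was tuned towards release of inner vascular cells even where this cost outer cells, so shares of cells describe the sorted suspension and not the intact root. The sorted cells were encapsulated with the 10x Genomics droplet chemistry that tags the 3' end of transcripts. All 3 libraries carry the same labels apart from the replicate number, which was taken from the sample titles because the description field gives replicate 1 for each of them. Nothing in the labels says whether the replicates came from separate plants, digestions or days, so p-values measure only the spread between these libraries, which may be technical.

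The authors deposited, for each library, a matrix of raw UMI counts (unique molecular identifiers, which count captured molecules and not PCR copies) with 34262 rows and 1 column per cell. Per the submitters' processing notes, the matrices were made with Cell Ranger and the genome build TAIR10; the version, the annotation and the cell-calling settings are not given in the sources used here. The authors also deposited an aggregated count matrix of the same 5145 cells. Matched by barcode, it held every UMI of replicate 1, 91.9% of those of replicate 2 and 95.5% of those of replicate 3, and no entry exceeded that in the library's own matrix. It was used only for this comparison, and all other values come from the 3 separate matrices.

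The files used here do not pair matrix rows with gene identifiers. A name was not taken from a row's position, so each row stands for 1 unnamed gene and is given only by its row number, and no gene name or genomic position is stated. Lists of marker and pathway genes that had been fixed in advance were not used here for that reason, and clusters of cells carry numbers and no cell type names.

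The depth was 102806676, 81615765 and 90656761 UMIs in replicates 1, 2 and 3. A count of 0 in a whole library allows a level of up to 0.0292, 0.0368 and 0.0331 CPM (UMI counts scaled to a common library total), respectively, taking a limit of 3 counts. Intervals and limits cover counting error only. All deposited barcodes entered the analysis. Scrublet, run per library in scanpy, called 21 cells (0.408%) as doublets. A rate under 0.5% is too low to be taken as a working doublet call, so no cell was removed, and results were recomputed without the called cells and without each library's cells in the top 5% of doublet scores, 301 cells with ties included.

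The rows were divided at random (seed 1) into a set of 17131 rows used to define clusters and a held-out set of 17131 rows used to compare them, so that no row was tested that had helped to define a cluster. The same cells served both steps, and held-out rows can vary together with the rows that defined the clusters. The p-values therefore do not show that a cluster is a separate population. For clustering, counts were scaled to 10000 per cell and log-transformed, the 2000 most variable rows were reduced to 30 principal components, and Leiden clustering was run at resolution 0.8 on a graph of 15 neighbours (scanpy 1.11.5, scikit-learn 1.9.0, python-igraph 0.11.9), with no batch correction. Clusters are numbered by size. Raw counts were summed per library and cluster, which gave 75 sums from 25 clusters with 11 to 155 cells each. The held-out rows were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood test) with the library as a block, since each library holds every cluster. Each cluster was compared with the unweighted mean of the other clusters' fitted log levels, which for a row high in few clusters lies below the log of their mean CPM, and a row was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Of 13104 held-out rows with a UMI, 9201 passed the filter. The same fit gave an F-test over all clusters and tests of all 300 pairs of clusters.

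The test was first run on simulated sums with the real row means, library sizes and dispersions, in which 200 rows changed in the largest cluster and another 200 in the smallest; 8350 simulated rows passed the filter, with most but not all of the changed ones among them. In cluster 1, 95.7% of the tested rows raised 4-fold and 97.9% of those at 0.25 of the level elsewhere were called, and in cluster 25 the shares were 93.6% and 63.8%. At a true fold of 2, which lies on the threshold, 45.7% of raised rows were called in cluster 1 and 34.8% in cluster 25. Of unchanged rows, 0.0367% were called in either cluster. The simulation had no clustering step. It also changed few rows, whereas 5094 rows in cluster 1 and 4441 in cluster 25 passed the adjusted p in the real fit. The more rows pass, the looser is the cutoff in unadjusted p. The simulated shares of called rows therefore do not carry over to the real test.

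Shares of cells are given with exact Clopper-Pearson 95% intervals, and the table of clusters by libraries was tested by chi-square, which compares these 3 libraries and covers counting error only. Rows detected per cell were compared after each cell had been thinned at random to 10000 UMIs; no cell was shallower. Libraries were compared through log2(CPM + 1) of their summed counts and by a rule of size: rows with at least 100 UMIs in all libraries together whose CPM in 1 library was at least 2-fold above or below both others (0.01 CPM added to each). Values over libraries are means ± SD. The rows named were chosen by a rule set before the data were examined: over all cluster comparisons, the 2 rows with the largest rise and the 2 with the largest fall among called rows that averaged at least 50 CPM and moved the same way in all 3 libraries.

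Alternatives set before the data were examined were the median-ratio normalization, no filter on low counts, DESeq2 1.42.0, no library block, each library left out, called doublets left out, the 2 row sets exchanged, resolutions of 0.4 and 1.2, 30 neighbours, log values centred per library, 5000 UMIs in place of 10000, a pseudocount of 10 CPM, a minimum of 1000 UMIs, a fold of 1.5 and equal weights for clusters. Added after the data had been seen were leaving out the highest doublet scores, equal depth for every sum without and with equal cell numbers, a stricter rule for concentrated rows, and leaving out each library in the comparison of pairs, of rows at fixed depth, of the most abundant rows and of concentrated rows. In the simulated test, a first requirement on the share of rows changed 4-fold that had to be called was set higher than the share reached for falls in cluster 25, and was replaced by a limit on the error of the median fold; the low power there is the 63.8% given above.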

Results

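The data describe 5145 single cells of wild-type Arabidopsis root tips, taken when seedlings were 6 days old, in 3 replicate libraries of 1975, 1472 and 1698 cells. The series is titled for the control of epidermal responses to low phosphate by vascular transcription factors. These libraries hold a single genotype and growth condition, so the comparisons they allow are between replicates and between populations of cells. The libraries held 102806676, 81615765 and 90656761 UMIs. A median cell carried 37317, 40366.5 and 38508.5 UMIs in replicates 1, 2 and 3, and 6850, 6986 and 6986.5 rows of the matrix were detected in it, each row standing for 1 gene. The shallowest cells had 19289, 19487 and 20704 UMIs and the deepest had 422487, 433213 and 828701. Of the 34262 rows, 26307 had a UMI in at least 1 library, 23218 had one in every library, and 7955 had none in the 3 libraries together, which allows a level of up to 0.0109 CPM. The 10 most abundant rows took 4.73% ± 0.084 (SD, n = 3) of a library's UMIs and the 100 most abundant took 19.9% ± 0.043 (SD, n = 3). The single most abundant row, number 6568, was the same in all 3 libraries and took 0.869% ± 0.041 (SD, n = 3).

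The first comparison asks how far the replicate libraries resemble each other. Summed over all cells, their expression profiles were nearly superimposable. The Pearson correlation of log2(CPM + 1) across rows was 0.998 for each of the 3 pairs of libraries; rows are not independent replicates, so no p-value is attached. Of 19045 rows with at least 100 UMIs, 180 (0.945%) had a level in 1 library at least 2-fold apart from both others, where counting noise alone gave 0.45 rows on average in simulation. The simulation drew UMIs and not whole cells. It therefore leaves out the spread from which cells entered a library, and that part of the 180 rows is not known. Rows above both others numbered 30, 49 and 17 in replicates 1, 2 and 3, and rows below both others 29, 11 and 44. The order of the libraries depended on the rule: at 1.5-fold, 200 rows were above both others in replicate 1 and 123 in replicate 2, and with at least 1000 UMIs the numbers were 11 and 9. With a single library per replicate number these rows describe the libraries and were not tested. No 2 libraries were the same library deposited again: a chi-square test of the summed counts gave a statistic of 20.2, 22.4 and 12.5 per degree of freedom for the pairs 1 and 2, 1 and 3, and 2 and 3.

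The second comparison asks which populations of cells the root tips held and whether each replicate held them alike. Clustering on the rows set aside for that purpose divided the cells into 25 clusters, and every library contributed to each of them. The largest, cluster 1, held 7.72% ± 0.29 (SD, n = 3) of a library's cells, clusters 2 and 3 held 7.43% ± 0.21 and 7.34% ± 0.80, and the smallest, cluster 25, held 0.859% ± 0.19. These are shares of sorted protoplasts, after a digestion tuned towards inner vascular cells. No difference in the makeup of the libraries was detected beyond counting error (chi-square 51.2 on 48 degrees of freedom, p = 0.349), a test that compares these libraries only. The highest share in any library was a median of 1.22 times the lowest, from 1.04 times in cluster 5 to 1.82 times in cluster 22. In 24 of the 25 clusters the exact intervals of the 3 libraries overlapped. The exception was cluster 17, which held 3.75% of the cells of replicate 1 (95% interval 2.95 to 4.68), 2.31% of replicate 2 (1.60 to 3.21) and 2.12% of replicate 3 (1.49 to 2.92).

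Cluster 17 was closely related to clusters 10 and 20. The 3 clusters together made up 9.92% of the cells in replicate 1 (95% interval 8.64 to 11.3), 8.90% in replicate 2 (7.49 to 10.5) and 9.13% in replicate 3 (7.80 to 10.6), with intervals that overlapped. At a resolution of 0.4 the same cluster held 100% of the cells of clusters 17 and 20 and 65.9% of those of cluster 10. Shares are also subject to the depth at which barcodes were accepted as cells. In cluster 3, 60.7% ± 5.8 (SD, n = 3) of the cells lay within 25% of the shallowest cell of their library, against 18.04% of all cells and 4.45% ± 2.5 (SD, n = 3) in cluster 6.

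**Figure D1:**
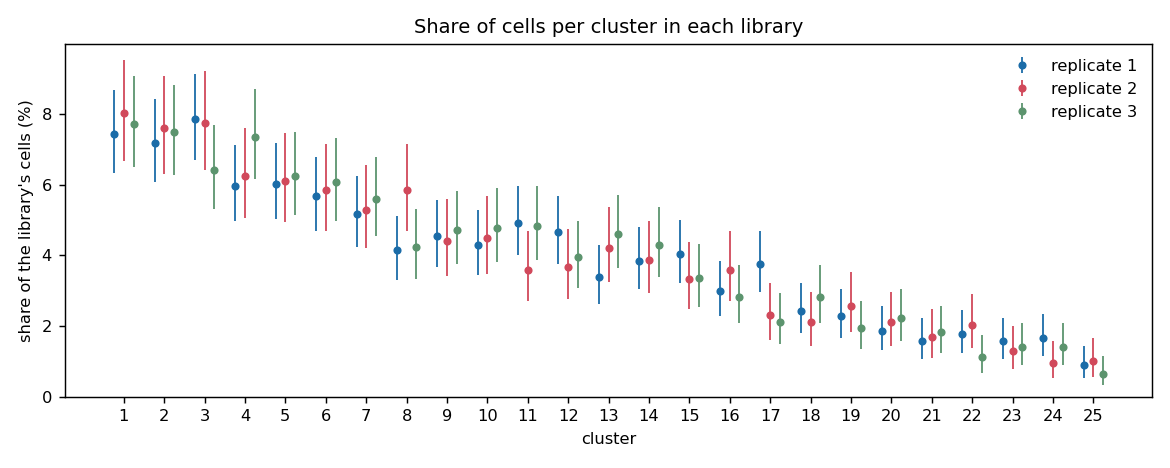
Share of each library's cells (%, vertical axis) in each of the 25 clusters (horizontal axis), 1 point per library with its exact 95% interval. The points of the 3 libraries lie close together, and cluster 17 is the only cluster in which the intervals do not all overlap (3.75%, 2.31% and 2.12%).

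The clusters differed in the number of transcripts captured per cell. Cells of cluster 6 had the most, with a median of 74864 ± 1747 UMIs (SD, n = 3), and cells of cluster 3 the fewest, with 23508 ± 149. The ratio of these clusters was 3.18 ± 0.072 (SD, n = 3) and lay between 3.14 and 3.27 in the single libraries. Clusters 13, 24, 2 and 15 followed cluster 6, with 62093 ± 4647, 61538 ± 12746, 58530.5 ± 5464 and 58525 ± 6772 UMIs. Cells of clusters 14, 16 and 10 were nearer to cluster 3, with 26209.5 ± 792, 27472 ± 1748 and 28246 ± 1249 UMIs. These are means of 3 library medians with their SD, and no test was made across libraries.

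At equal depth another order appeared. When each cell was thinned to 10000 UMIs, cells of cluster 16 showed the most different rows, a median of 3986 ± 42 (SD, n = 3), followed by cluster 11 with 3853 ± 17 and cluster 9 with 3852 ± 43. Cells of cluster 25 showed the fewest, 2773 ± 50, followed by cluster 23 with 2911 ± 164. The ratio of cluster 16 to cluster 25 was 1.44 ± 0.012 (SD, n = 3) and lay between 1.43 and 1.45 in the single libraries. Cluster 6, first in UMIs, showed 3406 ± 40 rows. Without thinning, the most rows were detected in cluster 6 (8656 ± 89) and the fewest in cluster 3 (5250 ± 39). Rows detected include any from free RNA in the droplets, which was not estimated. The replicates themselves were alike at equal depth, with medians of 3447, 3464 and 3500 rows over all cells of replicates 1, 2 and 3. The 100 most abundant rows took 36.0% ± 0.87 (SD, n = 3) of the UMIs in cluster 25, the highest share of any cluster, and 19.2% ± 0.34 in cluster 16. For the 10 most abundant rows, clusters 3, 14, 7 and 1 stood higher, from 11.2% to 11.9%, than cluster 25 with 10.5% ± 0.70.

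**Figure D2:**
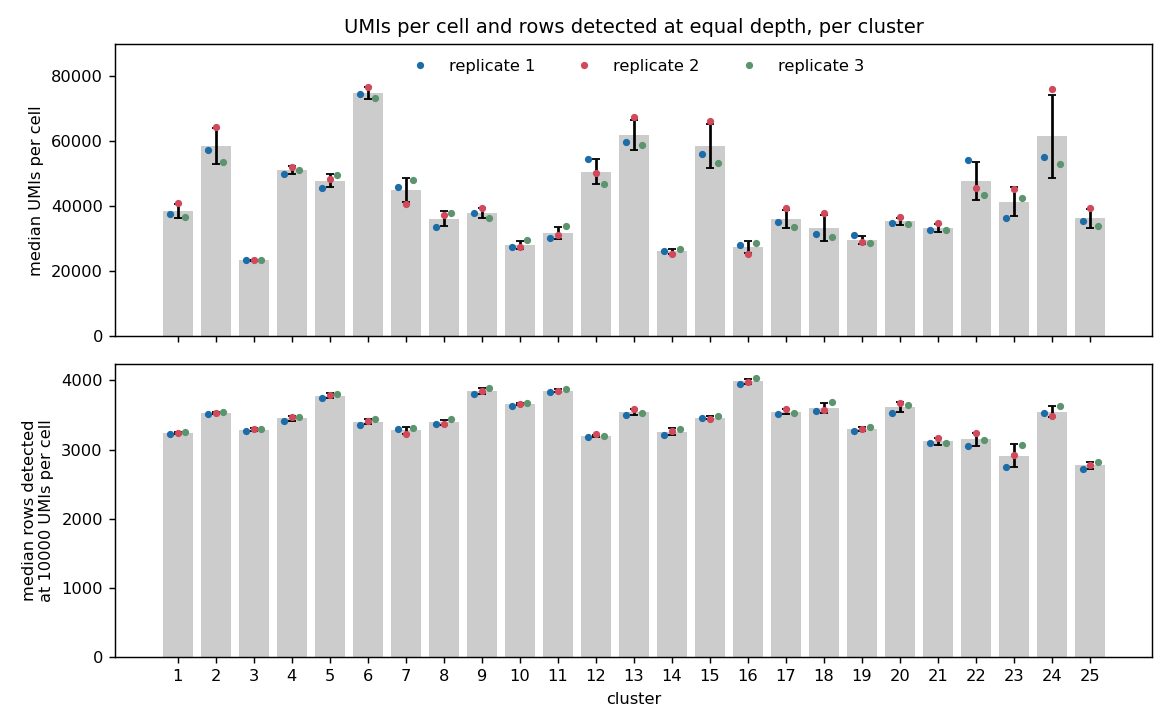
Median UMIs per cell (top) and median rows detected per cell at 10000 UMIs (bottom) for each cluster. Bars are means of the 3 libraries with SD, and points are single libraries. Cluster 6 leads in UMIs (74864), whereas cluster 16 leads in rows at equal depth (3986) and cluster 25 is lowest (2773).

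The third comparison asks how the populations differ in expression, in rows that had no part in defining them. Nearly every row that passed the filter on low counts varied between clusters: 9153 of 9201 tested rows (99.5%) differed over the 25 clusters by edgeR's quasi-likelihood F-test at an adjusted p under 0.05. Without the filter, 9989 of the 13104 held-out rows with a UMI differed. A median cluster had 2717 rows at least 2-fold above or below the mean log level of the other clusters, 1593 higher and 1100 lower as medians over clusters. Cluster 22, which held 84 cells, had 3728, of which 2016 were higher and 1712 lower. Cluster 2 had 3706, cluster 11 had 3583 and cluster 25 had 3566. At the lower end, cluster 19 had 2239, with 1392 higher and 847 lower, and cluster 6 had 2249. The order within each end was not stable: without replicate 1, cluster 22 had 3026, below cluster 25 with 3579, cluster 2 with 3544 and cluster 11 with 3317, and at equal depth cluster 25 had 2840 and cluster 22 had 2400. Rows higher outnumbered rows lower in all 25 clusters in this fit, but the direction turned in some of them under other settings. With DESeq2, lower rows were the more numerous in clusters 5, 6, 9, 12, 15 and 22 (in cluster 6, 872 higher and 1737 lower). With median-ratio normalization this held for clusters 6, 12 and 22, without replicate 1 for cluster 25 (1632 higher and 1947 lower), and without the highest doublet scores for cluster 23 (1379 higher and 2236 lower). In other clusterings each cluster was matched to the one with the largest share of its cells, which can be a merged one. Among clusters matched so, cluster 22 turned at resolutions of 0.4 (1822 higher and 3146 lower) and 1.2, with centring per library and with the row sets exchanged. Cluster 21 turned in the first 3 of these, cluster 25 in the last 3, and clusters 3, 12, 14, 15 and 23 with the row sets exchanged. Of all 70582 calls, 95.3% had the same direction in each of the 3 libraries. The calls were selected by a test on these same libraries, so such agreement was largely built in and is not a replication. Only 647 rows were called in no cluster.

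**Figure D3:**
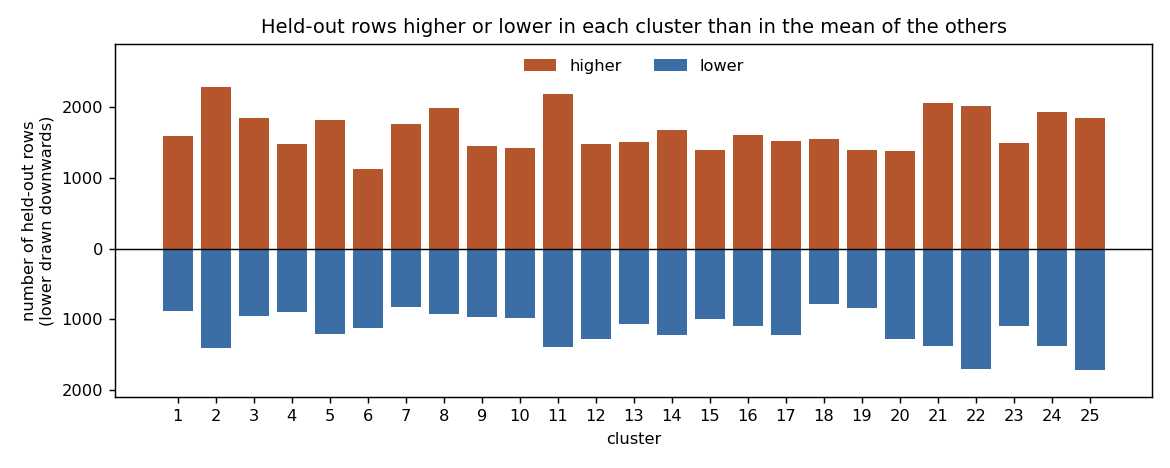
Number of held-out rows at least 2-fold higher (upwards) or lower (downwards) in each cluster than the mean log level of the other clusters, at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Counts of higher rows run from 1130 in cluster 6 to 2291 in cluster 2.

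For 825 rows (8.97% of those tested), more than 50% of the level summed over clusters lay in 1 cluster, and all 825 were called higher in that cluster. A share of this size nearly ensures that the fold rule is met, so the calls add little. The filter on low counts admits a row that is high enough in the 3 sums of 1 cluster. Rows could therefore enter the tests through that cluster alone, and the 8.97% depends on this. The top cluster of 782 of the 825 rows was the same in every library. Cluster 22 held 180 such rows, cluster 25 held 122, cluster 23 held 120, cluster 19 held 79 and cluster 21 held 64. These 5 clusters together held 68.5% of the concentrated rows and 7.87% of the cells. Cluster size alone did not set the number: cluster 24, with 71 cells, held 15 such rows and cluster 18, with 127 cells, held 4, whereas clusters 8, 16, 15, 14 and 3, with 240, 160, 186, 206 and 378 cells, held 42, 39, 34, 31 and 25. Clusters 2, 6, 10 and 17 held none. Clusters 10 and 17 differed from each other in only 171 rows, so a row high in both could hardly exceed 50% in either. The number of concentrated rows was not recomputed in other clusterings. Over all 9201 tested rows, the top cluster was the same in the 3 libraries for 48.2%, where a top cluster drawn at random in each library would give 0.16%. Clusters were defined over the 3 libraries together, so agreement above the random value was built in and does not test the clusters. Of the 5 clusters with the most concentrated rows, 4 also had the highest median doublet scores of all clusters, 0.0815 in cluster 25, 0.0806 in cluster 23, 0.0661 in cluster 22 and 0.0610 in cluster 21. Leaving out the cells with the highest scores lowered the share of cluster 25 from 0.859% to 0.438%, too few cells to test, and that of cluster 23 from 1.42% to 0.721%.

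The rows chosen by the fixed rule show the range of these differences. Row 31504 reached 1404 ± 224 CPM (SD, n = 3) in cluster 25, from 951, 744 and 750 UMIs in replicates 1, 2 and 3, and its mean CPM over the other clusters was 0.716 ± 0.24. The fitted log2 fold change, which is taken against the mean log level of the other clusters and so is not the ratio of these 2 values, was 12.27 ± 0.13 (SE; edgeR adjusted p = 3.33e-54), and 98.8% of its level summed over clusters lay in cluster 25. Row 22494 reached 4029 ± 470 CPM in the same cluster against a mean of 2.43 ± 1.0 CPM over the other clusters, and its fitted log2 fold change, on the same basis, was 12.24 ± 0.21 (SE; edgeR adjusted p = 2.08e-46). Each SE is the fitted log2 fold change divided by the square root of edgeR's F statistic. Row 31504 lay below 1.68 CPM, the limit of 3 counts in cluster 25, in 20 other clusters, with a median of 0.370 CPM. Row 22494 did so in 19, with a median of 0.970 CPM. Both fitted folds thus rest on very low levels elsewhere, and the SE may understate their uncertainty. Row 26196 had no UMI among the 5789489 of cluster 17, a limit of 0.518 CPM, and averaged 125 ± 28 CPM (SD, n = 3) in the other clusters. It was therefore at least 240.4-fold below that mean CPM, taking 3 counts over the whole cluster (edgeR adjusted p = 0.00215). That average rested mostly on cluster 23, where the row stood at 2828 CPM, and the median of the other clusters was 2.17 CPM. Its call was lost when all sums were thinned to equal depth (edgeR adjusted p = 1). Row 14056 had no UMI among the 1780934 of cluster 25, a limit of 1.68 CPM, and averaged 55.8 ± 3.1 CPM over the other clusters, a mean at least 33.1-fold higher, with its highest level in cluster 14 (410 CPM) and the next in cluster 3 (264 CPM). The median of the other clusters was 4.73 CPM, and 6 of them lay below the limit of 1.68 CPM, so the average rested on a few clusters. The last call had the highest adjusted p of these rows (edgeR adjusted p = 0.0391). It was lost at equal depth and when any 1 library was left out, with edgeR adjusted p of 0.0996, 0.0767 and 0.0956 without replicates 1, 2 and 3.

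The clusters were then compared in pairs. A median pair differed in 3779 of the 9201 rows. Such a count also depends on the cells and UMIs behind each cluster, and pairs were not compared at equal depth. Clusters 10 and 17 were the most alike, with 171 rows (1.86%), followed by clusters 17 and 20 with 435, clusters 10 and 20 with 681, and clusters 5 and 9 with 877. The pair 10 and 17 was also the nearest with each library left out, at 96, 156 and 110 rows without replicates 1, 2 and 3. Clusters 10 and 20 then differed in 413, 453 and 609 rows. Clusters 11 and 22 were the farthest apart, with 5580 rows (60.6%). Without replicate 1 the farthest pair was clusters 11 and 21, with 5221 rows, against 5131 for clusters 11 and 22. Clusters 25 and 22 had no close neighbour in this clustering: the nearest to cluster 25 was cluster 12, with 3056 rows, and the nearest to cluster 22 was cluster 21, with 2800. Cluster 25 was not separate in every clustering. At a resolution of 0.4, 1 cluster held 100% of its cells and 99.1% of those of cluster 12. With the row sets exchanged, 1 cluster held 100% of the cells of cluster 25 and 98.6% of those of cluster 12. The neighbour of cluster 25 depended on the libraries used, and was cluster 21 with 2805 rows without replicate 1, and cluster 18 with 2726 and 2591 rows without replicates 2 and 3. Without replicate 3, cluster 22 lay farther from its neighbour, at 2629 rows, than cluster 25 did.

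Average linkage on these counts, added after the pairs had been seen, divided the clusters into 2 groups. One group held clusters 2, 5, 9, 10, 11, 13, 16, 17, 20 and 24, with 2083 cells, and the other held the remaining 15 clusters. The median pair differed in 2515 rows within the first group, in 3335 rows within the second and in 4358.5 rows between them. The first group made up 40.7%, 39.4% and 41.2% of the cells of replicates 1, 2 and 3.

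**Figure D4:**
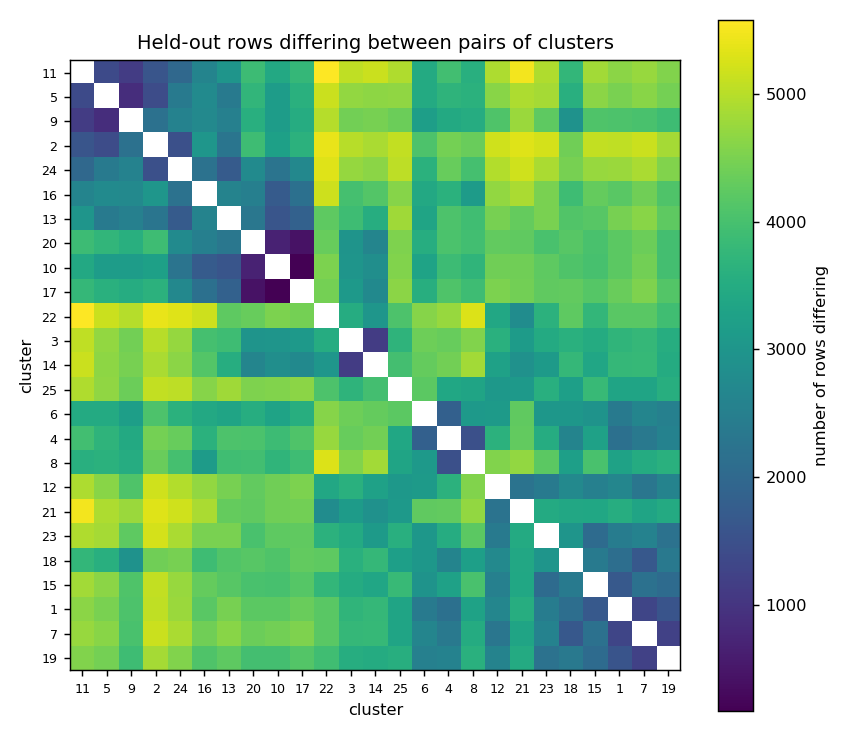
Number of held-out rows that differ between each pair of clusters (colour), with clusters ordered by average linkage on both axes. The 10 clusters at the upper left form a block of lower values, and the darkest squares are clusters 10 and 17 (171 rows) and clusters 17 and 20 (435 rows).

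Cluster profiles in the held-out rows were also compared between libraries. Each cluster's profile in 1 library was compared with the profiles of all 25 clusters in each other library, over 9523 rows with at least 100 UMIs. In 150 of 150 such comparisons the best match was the same cluster. Clusters were defined over the 3 libraries together, so such a match was largely built in and does not test the clusters. The median correlation was 0.978 with the same cluster and 0.930 with the nearest other cluster, and the lowest with the same cluster was 0.872. These correlations are across rows, which are not independent replicates. Clustering on the held-out rows instead gave 22 clusters. A median of 94.9% of a cluster's cells fell in 1 of these, and the lowest share was 51.7%, in cluster 8. Most cells of clusters 10, 17 and 20 fell in the same one.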

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

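All tests with equal depth, equal cells, the highest doublet scores left out, a stricter concentration rule, or libraries left out of the comparison of pairs, of the rows at fixed depth, of the top rows and of the concentrated rows were chosen after the results had been seen. The number of rows called in a cluster was 0.754 to 1.39 times the reported number under 13 alternatives. Among these were other normalization, DESeq2, no filter, no replicate block, other clusterings and each library left out. Fewer counts per sum changed it more. For other clusterings the count is that of the cluster with the largest share of its cells, which can be a merged one. With the row sets exchanged, clusters 10, 17 and 20 all took the 3207 of the same cluster, and other rows were tested. For other clusterings the range therefore does not show that a cluster's own count is stable. Rows differing across all clusters ranged from 9064 to 9128 with a library left out, the median of rows called per cluster from 2515 to 2640, and the median pair from 3541 to 3597; clusters 10 and 17 differed in 96 to 156 rows and clusters 11 and 22 in 5131 to 5588. Without the replicate block, 9140 rows differed across all clusters and the median per cluster was 2730, so the block changed no call count by 1.5 times. With every sum thinned to the same UMIs, the median fell to 1793 and the count moved by over 1.5 times in 16 clusters, to 1646, 2368, 1458, 1923, 1449, 1668, 1906, 1560, 2318, 1793, 1622, 1884, 1532, 1764, 1775 and 2400 in clusters 1, 2, 4 to 9, 11 to 17 and 22. With equal cells as well, 5078 rows differed across all clusters, the median was 1370, and clusters 1 to 25 had 1420, 1892, 1425, 1080, 1281, 1088, 1287, 1350, 1159, 1092, 1739, 1370, 1285, 1512, 1057, 1380, 1457, 1179, 1260, 1346, 1892, 1713, 1456, 1717 and 2211. Fewer rows then passed the filter, 5185 in place of 9201. The median was 2717 of 9201 tested rows as reported, 1793 of 6637 at equal depth and 1370 of 5185 with equal cells as well. The share of tested rows called therefore fell much less than the count. The tested rows differed between these settings, and how much of the fall came from the filter was not tested. The order of clusters by this count correlated with the reported one, although cluster 25 then had the most rows and cluster 15 the fewest (across clusters, Spearman's rho 0.85 and Pearson's r 0.889, permutation p = 2e-05 each, the smallest 100000 permutations can give; rho 0.83 and r 0.887 without the 2 clusters farthest from the median). Both counts came from the same clusters and rows, and 1 from a part of the other's cells, so a correlation was near certain beforehand. The permutation p therefore does not show that the order is free of cell number or depth. Of all calls, 59.3% were higher, against 53.5% with DESeq2 and 68.6% at equal cells and depth. The ratio of rows at equal depth was 1.42 at 5000 UMIs and 1.43 to 1.44 with a library left out. The mean correlation of libraries was 0.996 with clusters weighted equally and 0.998 with a library left out. Rows apart between libraries numbered 33 with at least 1000 UMIs, 748 at 1.5-fold and 357 with clusters weighted equally, and 405 rows had over 75% of their level in 1 cluster. The number of clusters was 17, 29, 21, 22 and 27 at resolution 0.4, at 1.2, with 30 neighbours, with row sets exchanged and with centring. The chi-square p for shares was 0.316 to 0.486 with a library left out, 0.394 with centring, 0.278 without called doublets and 0.108 without the highest doublet scores. The lower level of rows 14056 and 26196 was not called at equal depth (adjusted p = 1 for both), where fewer UMIs were available. Without the highest doublet scores, cluster 25 had too few cells to test and its share was 0.438%, and that of cluster 23 was 0.721%. The rule for rows apart needs 3 libraries and was not run with 1 left out.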

Other observations

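The tests of depth between libraries and of doublets, and the shuffling of cluster names, were chosen after the results they bear on had been seen; the tests of random cell draws and of abundant rows were set before theirs. The 2 groups of clusters seen in the pairwise comparison also differed in the number of rows detected per cell at equal depth. At 10000 UMIs per cell, clusters of the first group (2, 5, 9, 10, 11, 13, 16, 17, 20 and 24) showed 3691 ± 165 rows (SD over 10 clusters) and the other 15 clusters 3255 ± 212, a difference of 436 rows (permutation test over clusters, two-sided, p = 2e-05, the smallest 100000 permutations can give). The lowest cluster of the first group, at 3530 rows, stood above all of the second except cluster 18, at 3601. Clusters are not independent replicates, and the groups were drawn from expression in the same cells. UMIs per cell did not follow the groups, with 42715 ± 13694 and 41788.5 ± 13423 (permutation p = 0.858). One technical explanation is that a few very abundant rows took more of the UMIs in the second group, where the top 100 rows held 28.3% ± 3.8 against 23.8% ± 2.6. With each cluster's 100 most abundant rows removed before thinning, the difference was still 357 rows (permutation p = 0.00014), so these rows may account for part of it but not for the whole. The share of free RNA in the droplets was not estimated, so the rows detected are not shown to be the cells' own transcripts. What distinguishes the groups biologically was not tested, since rows carry no gene names here.

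The 3 libraries resembled each other closely, and no difference in their shares of cells was detected beyond counting error. They did not, however, differ only as random draws of cells from 1 pool would. A pair of separate sets of 736 cells was drawn at random from each library, 20 times over, and the sets were compared over 14405 rows. The median absolute log2 ratio was 0.0737 ± 0.0031 (SD over draws) within a library and 0.103 ± 0.0013 between libraries, a ratio of 1.40 ± 0.043. Whether the excess came from library preparation, from the digestion or from the plants stays open, and the design names no biological difference between the libraries that could be tested.

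UMIs per cell differed 3.18-fold between clusters 6 and 3. Depth that varied between libraries cannot account for this, since the lowest ratio within a library was 3.14. Droplets with 2 cells remain open: the 5 clusters with the most UMIs had a lower median doublet score than the rest (0.0165 against 0.0242, a ratio of 0.683), but this pooled median reflects the large clusters 6 and 2 (0.0116 and 0.0114), while clusters 13, 15 and 24 lay above the rest (0.0370, 0.0459 and 0.0488), and a caller that marks 0.408% of cells cannot be relied on. The depth limit on barcodes removes shallow cells and could only have raised the median of clusters near it, such as cluster 3. A difference in RNA content or cell size may remain, as an untested explanation.

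Shuffling cluster names asks only whether sums of 1 cluster in the 3 libraries were more alike than sums of unlike clusters. The sums came from clusters made over all libraries to separate these same cells, so the outcome was largely set in advance. The clustering step was not repeated, so chance in the clustering itself cannot be excluded. Cluster names were shuffled within each library 24 times and 4 shuffled clusters were tested in each. For each of the 25 clusters the real grouping was the only 1 of 97 splits with as many rows; the lowest real count was 2239 and the highest of the others 869. For the F-test over all clusters it was the only 1 of 25 splits, with 9153 rows against at most 1622. Why some shufflings called many more rows than others was not tested.

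Rows that lie next to each other in the matrix had more similar cluster profiles than distant rows. Over rows with at least 1000 UMIs, the mean correlation of profiles across the 25 clusters was 0.1502 for 7185 adjacent pairs, 0.105 at a distance of 2 rows, 0.0802 at 3, 0.0594 at 10 and 0.0599 at 1000, where random pairs gave 0.057 ± 0.0047 (SD over 100 random pairings). Without the 384 adjacent pairs correlated above 0.8, the mean was still 0.109, against 0.0416 at a distance of 1000 rows treated alike. What the order of rows represents is not given in the files used here.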
